A study of Mus musculus with 6 samples.

How the data were processed

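Total RNA from Tregs of spleen and lymph nodes was extracted with a Qiagen RNeasy kit and made into libraries with a KAPA RNA HyperPrep kit that depletes ribosomal RNA (RiboErase), per the labels' protocols. The authors deposited a table of raw counts per gene symbol, with 1 column for each of the 6 libraries. The values were whole numbers that summed to 13918321 to 17249898 per library. The submitters' processing notes name HISAT2 2.2.1, the mouse build mm10 and Cell Ranger, without saying what each was used for. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here, so counts of genes that overlap, lie antisense to each other or have near-identical copies are uncertain. Wrongly split reads would alter the level of such genes in either genotype.

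The table held 24421 genes, of which 8113 had 0 counts in every library, and no line stood for anything other than a gene. Columns were matched to samples by the sample titles. No libraries of a genotype agreed within sampling noise (chi-square per degree of freedom of 6.98 to 36.9 for pairs within a genotype), so each counted as 1 replicate. The replicate numbers 1, 3 and 5 and 6, 7 and 8 did not pair the genotypes.

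Genes were kept by filterByExpr with its defaults, which left 11932 genes. Counts were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, Srebp2cKO minus Srebp2WT, on all 6 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at a false discovery rate of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels of genes are TMM-scaled CPM, and sums of cell type markers are CPM of total counts without TMM factors. The common dispersion was 0.0112, and the first principal component held 56.4% of the variance. Counting intervals and the floor of 3 counts per library cover counting error only, since reads without molecular identifiers are not independent molecules.

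The 35 gene lists were written from textbook knowledge. They cover cholesterol biosynthesis, sterol uptake and feedback, fatty acid synthesis, LXR targets, isoprenoids and prenylation, Treg identity, effector and resting Tregs, T cell receptor response, proliferation, conventional effector T cells, interferon response, apoptosis, p53 targets, glycolysis, ATF4 response, unfolded protein response, oxidative phosphorylation, the mitochondrial genome, homing receptors, immediate early and heat shock genes, ribosomal proteins, replication histones, structural RNAs, sex-linked transcripts and markers of B cells, plasma cells, myeloid cells, dendritic cells, natural killer cells, CD8 T cells, gamma delta T cells, erythroid cells, platelets and stroma. The mitochondrial list had 0 genes in the table and was not analysed here. Lists with at least 3 tested genes (27 of 35) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Of these, 2 were called higher and 6 lower, and with an estimated correlation 0 were called (0.0782 was the smallest adjusted p). Members were also counted by their adjusted p over all genes and adjusted over the list alone.

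The grouping, the tests, the lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. Named genes were Srebf2 and Foxp3, all cholesterol synthesis genes that passed, and up to 4 members of each other list with the smallest p. To these were added the 10 largest changes in each direction among genes that passed, had a mean log2 CPM of at least 1 and had all 3 libraries of 1 genotype above those of the other, leaving out predicted models and immune receptor segments. The results of some genes that this rule names are not reported here. Single values per library were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

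The alternative settings fixed at that point were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, robust dispersion, no filter, a filter of at least 1 CPM in 3 libraries, abundant RNAs left out, a log2 fold change of at least 1, a false discovery rate of 0.1, fry, a rank-based set test, an estimated correlation and leaving out each library. After seeing the data, a GC correction was added, alone and with each library left out, together with a count outside regions of clustered calls. It removed a loess trend (span 0.3) of log2 CPM on transcript GC from each library as offsets.

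Positions, transcript GC and lengths came from GENCODE M21 on GRCm38 (23376 genes by symbol) and RefSeq on the same build (958 more), which left 24054 genes with GC and length. Large changes were counted in windows of 50 consecutive tested genes and compared with 1000 random placements. Sequence shared within the clustered stretches was counted as words of 50 bases, on either strand, that transcripts of more than 1 gene held. The tests were tried on simulated counts of 11820 genes with the measured means and library sizes. They recovered 2% of genes changed 1.25-fold, 64% at 1.5-fold, 81.6% at 2-fold and 95.8% at 4-fold, and 9.16% of 131 calls were false. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and biopython 1.88 was used for positions, alignments and plots.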

Results

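RNA was sequenced from regulatory T cells (Tregs), the CD4 T cells defined by the transcription factor Foxp3, taken from the spleen and lymph nodes of mice. The series holds 6 libraries, 3 labelled Srebp2WT (replicates 1, 3 and 5) and 3 labelled Srebp2cKO (replicates 6, 7 and 8). Per the labels, Srebp2cKO animals carried floxed alleles of the gene for SREBP2, with a Cre recombinase and yellow fluorescent protein at Foxp3, and Srebp2WT animals carried the same Cre without the floxed alleles. The Cre alleles were given as +/+ in Srebp2WT and +/- in Srebp2cKO, so Cre dose differed with the Srebf2 genotype. Counts assigned to genes totalled 15547538, 15500860 and 14694290 in the Srebp2WT libraries and 13918321, 15639282 and 17249898 in the Srebp2cKO libraries, and 14158 to 14689 genes had at least 1 count. Nothing in the labels says that the 3 libraries of a genotype came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The comparison asks how the transcriptome of Tregs differs when SREBP2, the transcription factor that activates cholesterol synthesis and uptake genes, is lost.

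Srebf2, the gene for SREBP2, lies on chromosome 15 from 82147181 to 82205379 (GRCm38). It fell to 6.66% of its Srebp2WT level, from 185 ± 10.9 to 12.4 ± 1.56 CPM (counts scaled to library size; mean ± SD, n = 3 libraries in each genotype here and below). The libraries held 3043, 2980 and 2548 Srebf2 counts in Srebp2WT and 187, 197 and 183 in Srebp2cKO. The log2 fold change was -3.91 (SE 0.11, 95% interval -4.14 to -3.67, edgeR adjusted p = 1.5e-08). Which exons the floxed allele removes is not given in the sources used here, so the remaining counts cannot be assigned to intact or deleted transcripts. Foxp3 is X-linked, and all libraries held Xist and 0 counts of 4 Y-linked genes, so +/- animals can have Tregs without an active Cre allele. The sort gate is not given in the sources used here, and whether such cells entered the Srebp2cKO libraries is not known. If they kept Srebf2 at its Srebp2WT level, the 6.66% that was left allows them only a small share of these libraries. Foxp3, on chromosome X from 7573644 to 7595245, stood at 454 ± 11.5 CPM in Srebp2WT and 435 ± 27.0 CPM in Srebp2cKO (log2 fold change -0.06, 95% interval -0.23 to 0.10, adjusted p = 0.611).

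Srebp2cKO Tregs had lower transcripts for cholesterol synthesis, lower transcripts of effector Treg genes such as Klrg1 and Tigit, and higher transcripts of resting Treg genes such as Bcl2 and Klf2. These list calls were made with a preset correlation and were not made with an estimated one (adjusted p = 0.0782, 0.550 and 0.550 with an estimated correlation). The estimate was 0.015 for the cholesterol list, near the preset 0.01, against 0.44 for the effector and 0.37 for the resting list. With fry, the cholesterol list passed (adjusted p = 3.0e-04) and the effector and resting lists did not (adjusted p = 0.0635 for each). The rank-based set test kept the calls of all these lists. Of 11932 genes tested, 283 were higher and 506 lower in Srebp2cKO at a false discovery rate of 0.05 with edgeR. With scaling to total counts alone, 184 were higher and 570 lower, a share of 24.4% higher in place of 35.9%. Single libraries moved the count by more than 1.5 times: 167 genes passed without Srebp2WT replicate 1, 184 without Srebp2WT replicate 3, 298 without Srebp2cKO replicate 7, 439 without Srebp2cKO replicate 8 and 1487 without Srebp2cKO replicate 6.

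Cholesterol synthesis genes are textbook targets of the deleted factor. Of 20 enzymes tested, 11 fell and 0 rose, and 13 were lower when adjusted over the list alone. The median log2 fold change of the list was -0.55 (camera adjusted p = 1.7e-10), and adjusted p = 0.0782 with an estimated correlation. Sqle, squalene epoxidase, fell from 14.9 ± 2.04 to 0.677 ± 0.513 CPM (log2 fold change -4.49, SE 0.33, adjusted p = 6.0e-05). Idi1 fell by 1.67 and Cyp51, lanosterol demethylase, by 1.63 on the log2 scale. Smaller falls were measured for Fdps (-0.85), Mvk (-0.82), Fdft1 (-0.81) and Msmo1 (-0.71). Hmgcs1 (-0.47) and Dhcr7 (-0.38) also passed.

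**Figure D1:**
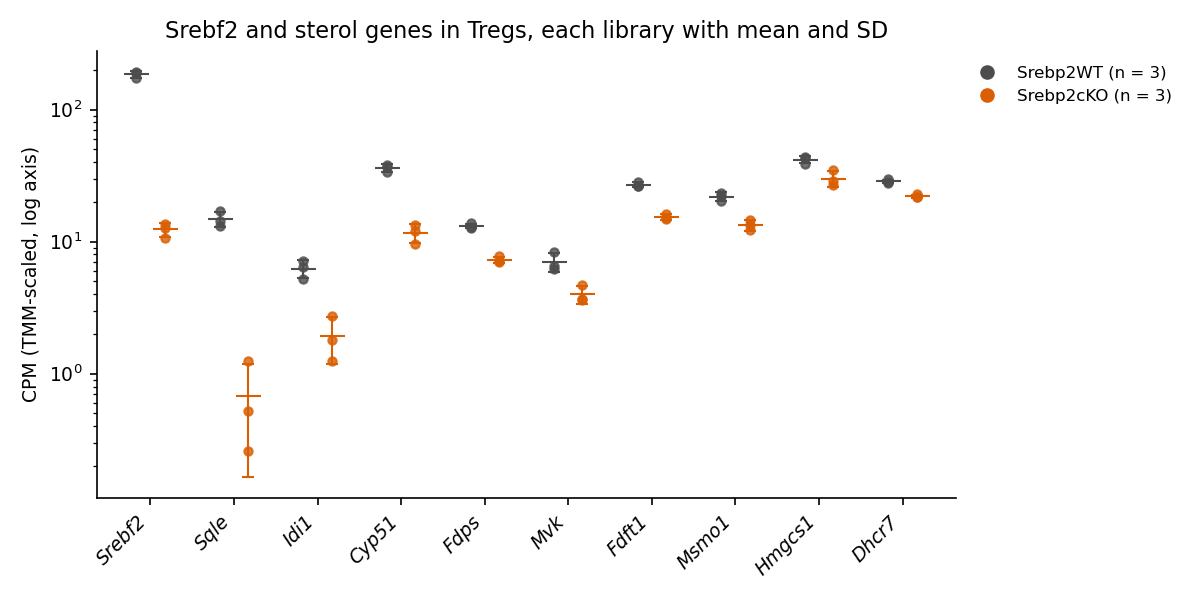
Levels of Srebf2 and 9 cholesterol synthesis genes in CPM on a log axis, with 1 point for each of the 3 Srebp2WT (grey) and 3 Srebp2cKO (orange) libraries and bars for the mean and SD. Of the genes drawn, Sqle and Srebf2 show the widest gaps (log2 fold changes of -4.49 and -3.91), and Hmgcs1 and Dhcr7 the narrowest (-0.47 and -0.38).

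Among 12 tested genes of sterol uptake and feedback, 3 fell and 0 rose, and 4 were lower and 2 higher when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.0750, median -0.15). Insig1, a sterol-sensing regulator of SREBP processing, and Stard4, a sterol transfer protein, fell by 0.72 and 0.59 on the log2 scale. Npc2, a lysosomal cholesterol carrier, had a log2 fold change of 0.28 and did not pass (adjusted p = 0.0529). Of 12 fatty acid synthesis genes, 4 fell and 0 rose, and 5 were lower when adjusted over the list alone (median -0.17, camera adjusted p = 0.0449, and adjusted p = 0.550 with an estimated correlation). These 4 were Scd2 (-0.69), Fasn (-0.67), Mid1ip1 (-0.84) and Acaca (-0.62).

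No gene passed in edgeR among 10 genes of cholesterol efflux and LXR targets (camera adjusted p = 0.260) or among 16 genes of isoprenoid synthesis and prenylation (camera adjusted p = 0.519). At an unadjusted p under 0.05 there were 2 and 5 genes in these lists, against 3471 of all 11932 tested genes. DESeq2 called 0 and 1 of them, and limma-voom 0 in both.

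Of 31 effector Treg genes tested, 17 fell and 0 rose, and 25 were lower when adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 1.7e-10, and adjusted p = 0.550 with an estimated correlation). Klrg1, a receptor of terminally differentiated effector Tregs, fell from 24.6 ± 9.55 to 3.15 ± 1.77 CPM (log2 fold change -2.93, SE 0.38, adjusted p = 0.00245). Tigit, an inhibitory receptor, fell from 59.6 ± 9.98 to 18.7 ± 7.86 CPM (log2 fold change -1.66, SE 0.24, adjusted p = 0.00443). The chemokine receptor Cxcr3 fell by 1.10 and the checkpoint receptor Pdcd1 by 1.07 on the log2 scale.

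Of 18 resting Treg genes, 6 rose and 0 fell, and 14 were higher and 1 lower when adjusted over the list alone (median 0.38, camera adjusted p = 2.0e-05, and adjusted p = 0.550 with an estimated correlation). Bcl2, an anti-apoptotic gene, rose from 462 ± 39.6 to 662 ± 72.2 CPM (log2 fold change 0.52, SE 0.10, adjusted p = 0.0180). Klf2 (0.46) and Foxp1 (0.38) also rose. The 16 Treg identity genes moved both ways, with 2 higher and 3 lower, and 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.593). Il2ra, the interleukin-2 receptor alpha chain, rose from 691 ± 11.4 to 920 ± 22.1 CPM (log2 fold change 0.41, SE 0.07, adjusted p = 0.0101), and Gpr34 rose by a log2 fold change of 0.49, while Izumo1r (-0.43) and Nrp1 (-0.32) fell. The call for Nrp1 was lost in each of the 6 fits that left out 1 library.

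**Figure D2:**
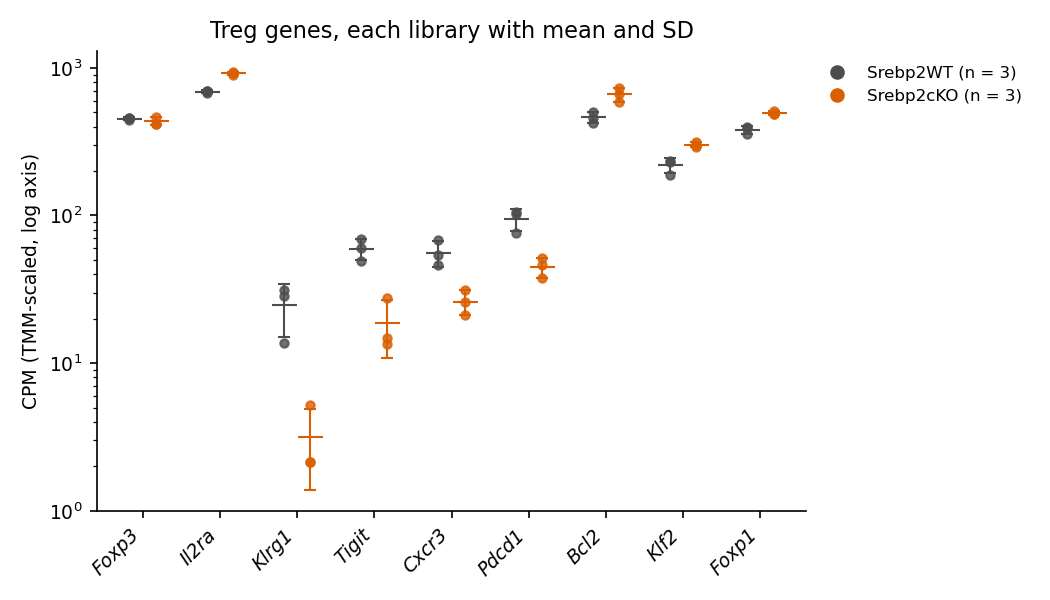
Levels of Treg genes in CPM on a log axis, with 1 point for each of the 3 Srebp2WT (grey) and 3 Srebp2cKO (orange) libraries and bars for the mean and SD. Foxp3 overlaps between genotypes (454 and 435 CPM), the effector genes Klrg1, Tigit, Cxcr3 and Pdcd1 lie lower in Srebp2cKO, and Il2ra, Bcl2, Klf2 and Foxp1 lie higher.

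Of 29 interferon-stimulated genes, 6 fell and 0 rose, and 18 were lower when adjusted over the list alone (median -0.43, camera adjusted p = 3.9e-05, and adjusted p = 0.550 with an estimated correlation). The antiviral genes Rsad2 (-1.10), Oas1a (-0.92), Rtp4 (-0.44) and Ifit1 (-0.43) were among those that fell. Of 77 ribosomal protein genes, 26 rose and 1 fell, and 45 were higher and 1 lower when adjusted over the list alone (median 0.29, camera adjusted p = 5.4e-14, and adjusted p = 0.550 with an estimated correlation). Rpl5 rose from 908 ± 101 to 1539 ± 217 CPM (log2 fold change 0.76, adjusted p = 0.00638), and Rps4x (0.52), Rpl36a (0.51) and Rps23 (0.41) rose with it. The 1 gene that fell was Rpl3, named after its values were seen. Rpl3 lies in the stretch of chromosome 15 around Srebf2 where large changes clustered, described below. The camera test also called 36 proliferation genes lower (median -0.36, adjusted p = 0.00335, and adjusted p = 0.736 with an estimated correlation), although only Tyms, thymidylate synthase (-0.60), passed on its own, both over all genes and when adjusted over the list alone. The call for Tyms was kept in only 1 of the 6 fits that left out 1 library. Of the 36 genes, 5 had positive log2 fold changes. The list's mean score per library overlapped between the genotypes, at 0.39, -0.23 and 0.36 in Srebp2WT and -0.21, -0.42 and 0.11 in Srebp2cKO. Mki67 had a log2 fold change of -0.78 and did not pass (adjusted p = 0.102). Replication histone genes, whose transcripts lack a poly(A) tail, were called lower (62 tested, 3 fell, 0 when adjusted over the list alone, median -0.48, camera adjusted p = 2.1e-05). That list had adjusted p = 0.736 with an estimated correlation, and the 3 genes were Hist1h3e (-1.08), Hist1h3i (-1.28) and Hist1h4k (-0.65). Its scores overlapped too, at 0.47, -0.02 and 0.29 in Srebp2WT and -0.15, -0.71 and 0.12 in Srebp2cKO.

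**Figure D3:**
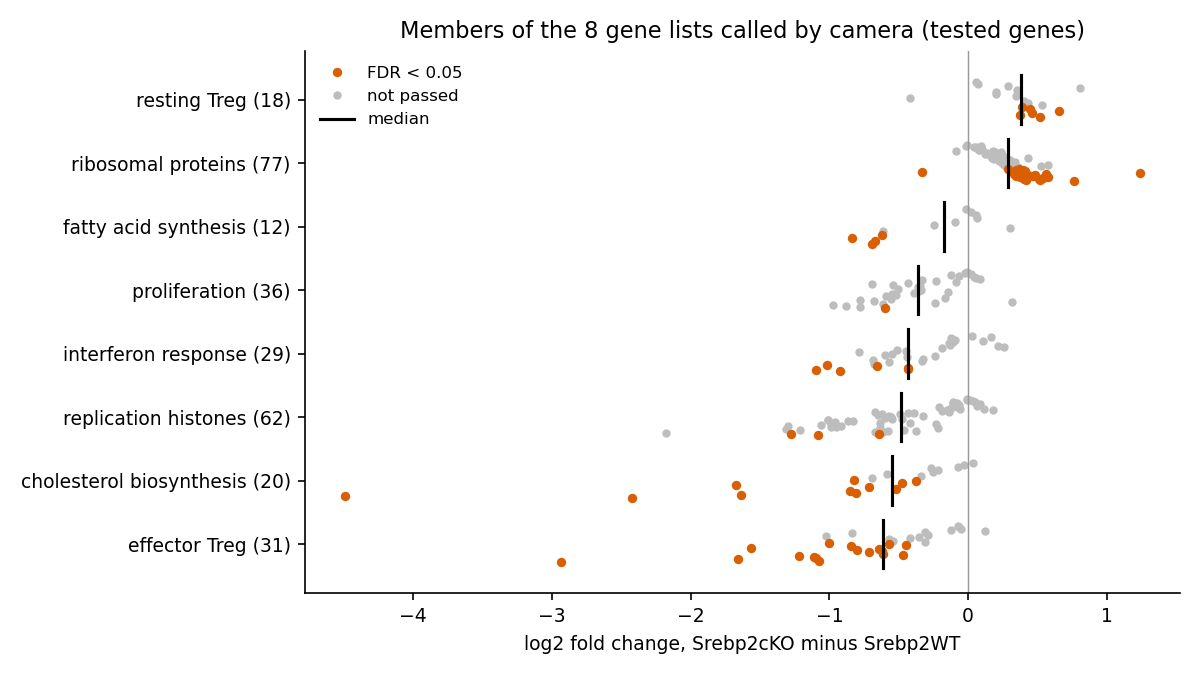
Log2 fold changes (Srebp2cKO minus Srebp2WT) of the tested members of the 8 gene lists called by camera, with 1 point per gene, orange where the gene passed a false discovery rate of 0.05 and grey where it did not, and a black line at each list's median. The number of tested genes follows each list's name, and medians run from -0.61 for effector Treg genes to 0.38 for resting Treg genes.

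The other lists did not pass as groups. Of 19 T cell receptor response genes, Cd69 rose (0.53) and Cd83 (-0.86) and Bhlhe40 (-0.76) fell (camera adjusted p = 0.593, with 1 higher and 3 lower when adjusted over the list alone). Of 18 homing receptors, 4 fell, namely Gpr15 (-1.49), Itgb8 (-0.66), Itgb1 (-0.65) and Itgal (-0.43), and 4 were lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.346). Among 10 conventional effector T cell genes 1 rose, and 1 was higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.756). Among 18 apoptosis regulators Bik rose (2.57) and Bak1 fell (-0.41), and 2 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.967, with a median of -0.02 and a mean of 0.11). Aldoc fell (-1.79) among 20 glycolysis genes (camera adjusted p = 0.260), the 1 gene that also passed when adjusted over the list alone. Creld2 fell (-0.86) among 17 genes of the unfolded protein response (camera adjusted p = 0.725), where 2 were higher and 1 lower when adjusted over the list alone.

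No gene passed in edgeR among 38 oxidative phosphorylation genes (camera adjusted p = 0.0750), 15 ATF4 response genes (0.260), 13 p53 targets (0.724) or 18 immediate early and heat shock genes (0.931), over all genes or when adjusted over the list alone. At an unadjusted p under 0.05 there were 8, 3, 2 and 3 genes in these lists, against 3471 of all 11932 tested genes. DESeq2 called 1, 0, 0 and 1 of them, and limma-voom called 0, 1, 0 and 0.

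The genes with the largest rises, among those that passed, had a mean log2 CPM of at least 1 and were separated in all libraries, were led by Rprl3, an RNase P RNA-like gene, with 0 counts in every Srebp2WT library and 1016, 515 and 1098 in Srebp2cKO, at least 294-fold higher against a floor of 3 counts per library. Its longest transcript was 86.4% identical to Rpph1 over 257 aligned bases, so its count is uncertain. Next came Ifi204 (log2 fold change 6.01), Gdpd3 (5.51), Erdr1 (4.66), Mnda (3.24), Mtmr9 (3.07), Tnfrsf13c (2.92), Ly6k (2.88), Xlr3b (1.91) and Tmem108 (1.39). Gdpd3, a lysophospholipase D, rose from 3.22 ± 0.392 to 147 ± 21.8 CPM (SE 0.15, adjusted p = 1.5e-08). The largest falls reported by the same criteria were in Zan (-6.75), Apobr (-5.43), Sqle, Tgfb1i1 (-4.35), Srebf2, Slc7a10 (-3.36), Klrg1, Tshz2 (-2.76) and Nid2 (-2.62). Zan, which encodes the sperm protein zonadhesin, fell from 65.9 ± 16.7 to 0.590 ± 0.201 CPM (SE 0.28, adjusted p = 4.1e-07). Apobr had 0, 2 and 2 counts in Srebp2cKO, so its ratio rests on few counts.

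Large changes were not spread evenly over the genome. Of 217 genes placed on chromosomes 1 to 19 and X that passed with an absolute log2 fold change of at least 1, 28 (12.9%) lay in 3 stretches that held 1.2% of the tested genes. These were chromosome 14 from 50.8 to 54.9 Mb, chromosome 14 from 63.2 to 73.2 Mb and chromosome 15 from 79.8 to 83.0 Mb (GRCm38). The last holds Srebf2 at 82.15 Mb. Of its 8 other large changes, 6 lay at 79.79 to 80.00 Mb, where Apobec3 fell from 303 ± 12.7 to 49.8 ± 1.53 CPM (log2 fold change -2.61) and Cbx6 from 136 ± 16.2 to 40.8 ± 2.50 CPM (-1.73), while Tnfrsf13c, next to Srebf2 at 82.22 Mb, rose. Ccnb1ip1, at the edge of the first stretch, had 0 counts in every Srebp2WT library and 21, 47 and 48 in Srebp2cKO. That was at least 12.6-fold higher against the same floor. Its end at 50807732 overlaps Rpph1 (50807449 to 50807767), the gene that Rprl3 resembles, which held 14651 to 29268 counts per library. Transcripts of other genes in the stretch held 10.04% of its 50-base words. The count of Ccnb1ip1 is therefore uncertain too. Apobec3, Cbx6 and Ccnb1ip1 were chosen after their values were seen.

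**Figure D4:**
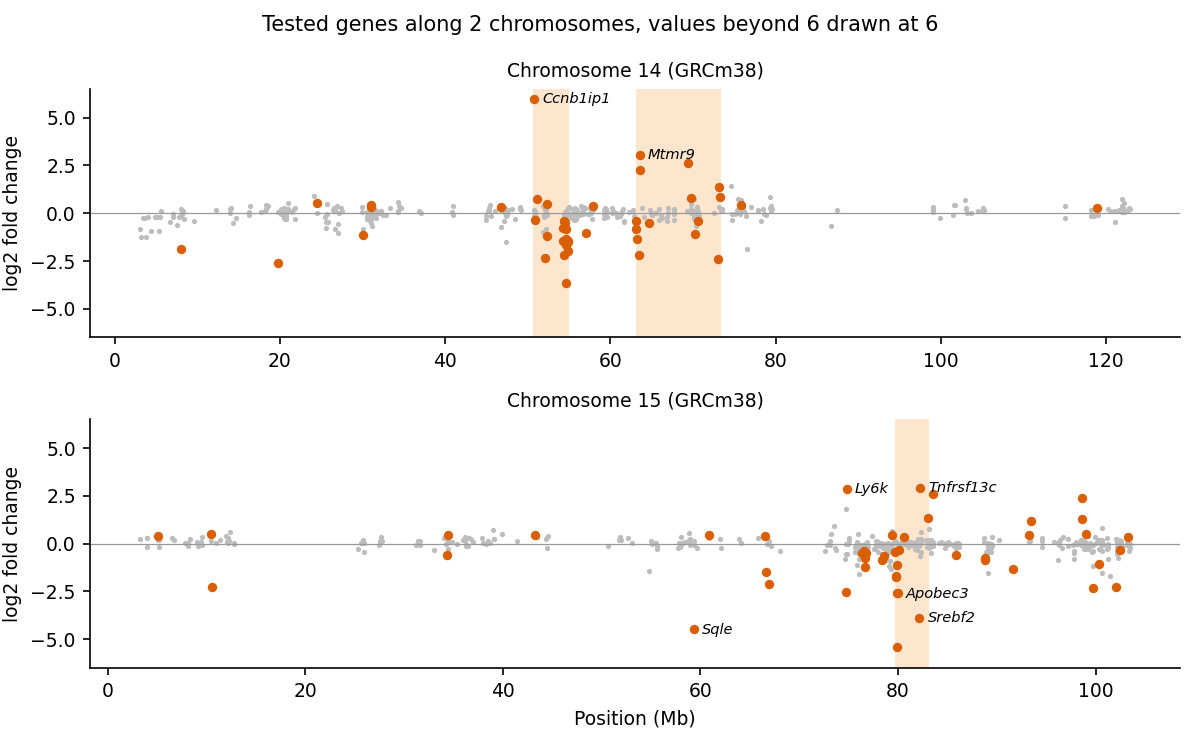
Log2 fold changes (Srebp2cKO minus Srebp2WT) of tested genes by position in Mb on chromosomes 14 and 15, orange where the gene passed a false discovery rate of 0.05, grey where it did not, with the 3 stretches of clustered large changes shaded. Ccnb1ip1, with 0 counts in Srebp2WT, is drawn at 6.

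Fold changes also followed the GC content of transcripts. The decile of genes with the lowest GC content held 84 higher and 9 lower calls (median log2 fold change 0.23), and the decile with the highest GC content held 4 higher and 116 lower (median -0.26). The Spearman correlation across 11839 genes was -0.50, where genes are not independent replicates. The slope of log2 CPM on GC, in log2 units per 10 points of GC, was 0.15, 0.18 and 0.02 in the Srebp2WT libraries and 0.01, -0.25 and -0.12 in the Srebp2cKO libraries. With this trend removed from each library, an alternative chosen after seeing the data, 221 genes were higher and 436 lower. Of the named genes that passed, 9 lost their call with that correction, namely Mvk, Dhcr7, Gpr34, Izumo1r, Cd69, Bak1, Cd79b, Hist1h3i and Hist1h4k.

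**Figure D5:**
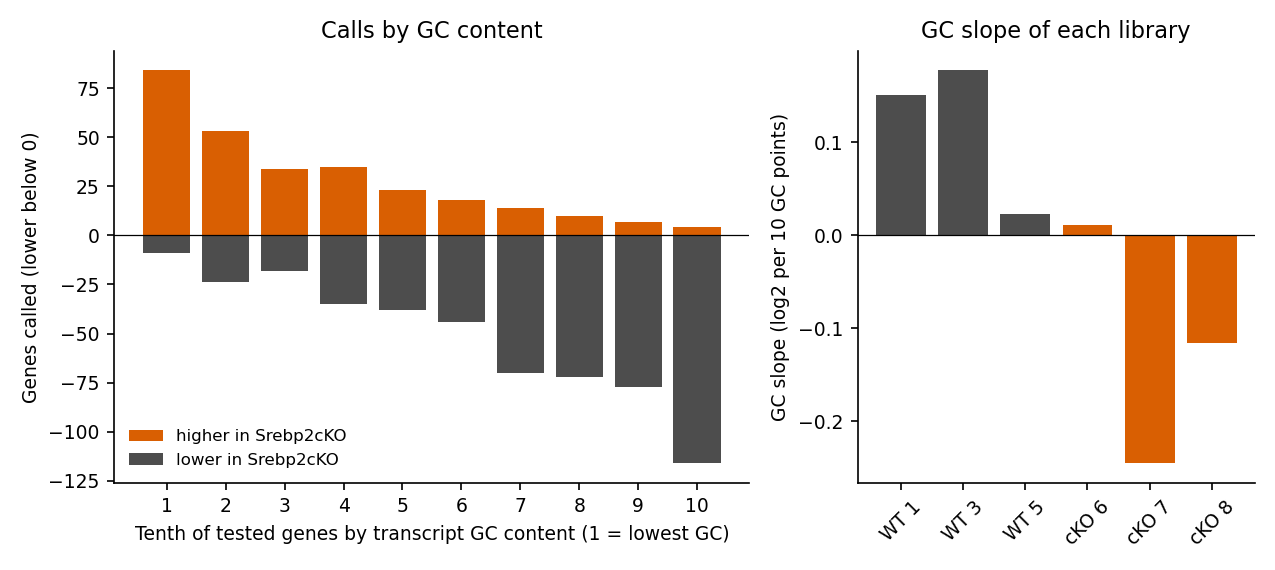
Left, genes called higher (orange, above 0) and lower (grey, below 0) in Srebp2cKO in each decile of tested genes by transcript GC content, from 84 higher and 9 lower in the lowest decile to 4 higher and 116 lower in the highest. Right, slope of log2 CPM on GC content in log2 units per 10 points of GC for each Srebp2WT (grey) and Srebp2cKO (orange) library, from 0.18 to -0.25.

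Several markers of other cells were low in all libraries, with at most 14 counts of Cd8a, 2 of Ms4a1, 5 of Lyz2 and 0 of Ncr1 in any. Sums of markers were scaled to total counts alone and single genes also by TMM, so a gene can exceed its sum. Summed B cell markers were 72.7 ± 13.0 CPM in Srebp2WT and 38.9 ± 5.16 in Srebp2cKO, and summed myeloid markers 69.0 ± 20.6 and 41.2 ± 3.86, each with exact permutation p = 0.1, the smallest possible for 3 against 3. Summed CD8 T cell markers were 7.25 ± 0.301 and 9.24 ± 0.892 CPM, and summed stromal markers 174.5 ± 6.35 and 222 ± 7.40 (exact permutation p = 0.1 for each). The most abundant myeloid marker, Cybb, stood at 60.7 ± 18.0 and 33.1 ± 2.96 CPM, and the most abundant B cell marker, Cd74, at 39.2 ± 7.84 and 17.7 ± 3.12 CPM. Pecam1 stood at 171 ± 4.18 and 224 ± 9.30 CPM among the stromal markers, and Cd8b1 at 7.02 ± 0.277 and 8.74 ± 0.924 CPM among the CD8 T cell markers. These sums differed between the genotypes alongside the effector, resting, interferon and proliferation lists. Of 5 tested B cell markers, 3 fell over all genes and when adjusted over the list alone, namely Cd22 (-1.52), Cd74 (-1.14) and Cd79b (-0.68), while the list did not pass (camera adjusted p = 0.260). Cybb fell (-0.87) among 4 myeloid markers (camera adjusted p = 0.725, median -0.07 and mean 0.02), where 1 was higher and 1 lower when adjusted over the list alone. Klrb1c fell (-1.36) among 3 natural killer cell markers (camera adjusted p = 0.489), where 2 were lower when adjusted over the list alone. Of 3 plasma cell markers, 0 passed in edgeR over all genes and 1 was lower when adjusted over the list alone (camera adjusted p = 0.563), with 1 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom.

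Lists with fewer than 3 tested genes had no group test. Of these, Pecam1 rose (0.39) among 2 stromal markers, while 0 of 2 dendritic, 1 CD8 T cell, 1 erythroid and 1 platelet marker passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom. No gamma delta T cell marker was tested. Xist stood at 2633 ± 194 and 2321 ± 111 CPM (log2 fold change -0.18, adjusted p = 0.187), and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in every library. The ribosomal RNA precursor Rn45s took 11.1 ± 1.27% of counts in Srebp2WT and 8.66 ± 2.48% in Srebp2cKO (exact permutation p = 0.2). Ribosomal protein genes took 3.96 ± 0.286% and 4.78 ± 0.0797% of counts (exact permutation p = 0.1). Of 5 structural RNAs, 0 passed in edgeR and 1 was lower when adjusted over the list alone (camera adjusted p = 0.736), with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom.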

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

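Of the alternatives, only the GC correction, its fits without 1 library and the count outside clustered regions were chosen after the results were seen. Srebf2 kept its direction and call throughout (-3.98 to -3.81 without 1 library). Of the 80 named genes that passed, 40 passed in all 6 fits without 1 library, 0 changed sign, and 71 passed with GC correction, 80 with DESeq2 and 78 with limma-voom. Tyms, Dhcr7, Cd79b, Klrb1c, Hist1h3i and Hist1h4k passed in only 1 of those 6 fits, and Nrp1 in 0. Hmgcs1 and Mvk were among the genes that passed in 2. Higher calls numbered 184 with total counts only, 620 with DESeq2, 473 with no filter, 31 (187 lower) at a log2 fold change of at least 1, and 861 (1032 lower) at a false discovery rate of 0.1. Without 1 library, 29 to 700 genes were higher and 135 to 787 lower, and with GC correction 51 to 261 higher and 198 to 503 lower. Fewer libraries and another number of tested genes enter these fits, and otherwise the cause was not tested. The weakest counts came without Srebp2WT replicate 1 (167 calls) or 3 (184). A depth of 13918321 to 17249898 counts limits genes with few counts. No paired analysis was possible because the genotypes share no replicate numbers.

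With an estimated correlation 0 lists were called higher and 0 lower, and with GC correction in addition 0 and 1 (cholesterol synthesis, adjusted p = 0.0320). With fry 0 were called higher and 3 lower, namely cholesterol synthesis, sterol uptake and fatty acid synthesis. The medians stayed the same where only the test changed: -0.55 for cholesterol synthesis, -0.17 for fatty acid synthesis (also lost with the rank-based test), -0.61 for effector Treg, 0.38 for resting Treg, -0.36 for proliferation, -0.43 for interferon response, 0.29 for ribosomal proteins and -0.48 for histones. With GC correction they were -0.16 for fatty acid synthesis, -0.55 for effector Treg, 0.32 for resting Treg, -0.39 for proliferation, -0.35 for interferon response, 0.31 for ribosomal proteins and -0.25 for histones. Adjusted p over the alternatives ran from 6.4e-13 to 0.0782 for cholesterol synthesis and from 3.4e-14 to 0.550 for effector Treg. Without 1 library, fatty acid synthesis ranged from -0.25 to -0.11 and proliferation from -0.58 to -0.22, the former losing its call without Srebp2WT replicate 3 or 5 or Srebp2cKO replicate 6 or 8, the latter without Srebp2WT replicate 5 or Srebp2cKO replicate 6. Proliferation moved by over 1.5 times without Srebp2WT replicate 1 or 3 or Srebp2cKO replicate 8. Histones ranged from -0.69 to -0.28 (-0.28 without Srebp2cKO replicate 7) and interferon response from -0.44 to -0.28 (-0.28 without Srebp2WT replicate 1). Fatty acid synthesis had a median of -0.43 with no filter. Sterol uptake, not called, passed with GC correction (adjusted p = 0.0043), with fry (3.0e-04) and without Srebp2cKO replicate 7, B cell markers passed with the filter of 1 CPM in 3 libraries (0.0403), and oxidative phosphorylation passed without Srebp2WT replicate 5 or Srebp2cKO replicate 7.

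Direction, as the test gave it, turned only for results that were not called. With GC correction it turned for the following, where log2 fold changes were 0.0731 for Foxp3 and 0.0707 for Rpph1, and medians 0.0129 for isoprenoids, 0.0104 for T cell receptor response, 0.0261 for apoptosis and 0.0247 for ATF4 response, with or without an estimated correlation (the isoprenoid and apoptosis lists turned from higher to lower by camera, against the sign of these medians). Some medians changed sign while camera kept its direction: glycolysis from -0.12 to 0.043 and structural RNAs from -0.29 to 0.0272 with GC correction, p53 targets from 0.03 to -0.0027 with total counts and -0.0026 with the filter of 1 CPM in 3 libraries, and myeloid markers from -0.07 to 0.354 with no filter and 0.351 with that filter. The rank-based test and fry put apoptosis lower (median -0.015), and fry put the unfolded protein response lower (median 0.0355). Without 1 library, medians ranged from -0.107 to 0.0701 for apoptosis, -0.0398 to 0.114 for the unfolded protein response, -0.10 to 0.23 for immediate early genes, -0.73 to 0.33 for myeloid markers and -0.55 to -0.0002 for natural killer markers. The cause was not tested.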

Other observations

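All tests of explanations and all splits below were chosen only after the results were seen.

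Tnfrsf13c, the BAFF receptor, rose from 0.604 ± 0.0549 to 4.64 ± 0.831 CPM, and Ifi204 and Mnda, neighbouring interferon-inducible genes on chromosome 1 at 173.75 and 173.90 Mb, rose by log2 fold changes of 6.01 and 3.24, while the interferon response list had a median of -0.43. Apobr and Gdpd3 lie close together on chromosome 7 at 126.58 and 126.77 Mb and went opposite ways (-5.43 and 5.51). Among the named genes, Itgal at 127.3 Mb (-0.43) and Tgfb1i1 at 128.25 Mb (-4.35) lie near them and fell. This part of chromosome 7 was not among the stretches of clustered large changes. Gpr15, a receptor for homing to the colon, fell from 13.1 ± 3.08 to 4.68 ± 0.601 CPM.

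The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 789 genes with edgeR and the highest other split 0, so 1 of 10 splits gave as many. In the other splits 99 to 2101 genes had an unadjusted p under 0.05, DESeq2 called up to 112 and limma-voom 0. For the real split these numbers were 3471, 1374 and 782. The 2101 and 112 came from the same split, Srebp2WT replicates 1 and 3 with Srebp2cKO replicate 6. Next highest were 503 and 12. Those replicates had the largest shares of Rn45s (11.75, 11.91 and 11.16% of counts, against 9.63, 6.20 and 8.63% in the others). Whether the 2 are related was not tested. For gene lists the outcome was different: the real split called 8 lists with camera, the highest other also 8, and 4 of 10 splits gave as many. The cholesterol synthesis list passed in 7 splits, with a smallest adjusted p of 0.00383 outside the real split against 1.7e-10 within it. For 3 lists the smallest adjusted p elsewhere lay below that of the real split: 7.1e-15 against 1.7e-10 for effector Treg, 2.2e-33 against 0.00335 for proliferation and 1.6e-22 against 2.1e-05 for histones. Effector Treg, ribosomal proteins and histones passed in 7, resting Treg, interferon response and proliferation in 6 and fatty acid synthesis in 1, the real split. Other splits mix the genotypes, so any difference between the genotypes widens the spread within their groups and makes gene calls less likely. They still hold part of that difference, and the preset correlation of 0.01 lies far below the estimate of 0.44 for the effector list.

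Fold changes followed GC content, and calls leaned with it. The trend as the whole cause of the calls is argued against by the correction, after which 63.1% of the calls kept their direction and passed, while 36.9% did not. GC bias that differs from library to library stays possible, since the slopes ranged over 0.2565 within Srebp2cKO, above the difference of the genotype means (0.2333). Within Srebp2WT they ranged over 0.155, below that difference. An effect of the genotype on GC-rich transcripts cannot be told apart from such bias. The slopes separated the genotypes by only 0.011 at their nearest, with an exact permutation p of 0.1, the smallest possible.

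Of the effector Treg genes 17 of 31 were lower and of the resting Treg genes 6 of 18 were higher, while both list calls were lost with an estimated correlation (adjusted p = 0.550 with an estimated correlation for each). GC bias between libraries as the cause is argued against by 19 effector genes that were still lower after the correction. A larger share of cells without Foxp3, as the whole cause, is argued against by Foxp3 itself. Its 95% interval reached down only to -0.23, above the effector median of -0.61. This holds only if Foxp3 transcripts per cell were alike in the genotypes, which was not measured. Cre dose at Foxp3 differed between the genotypes, and a smaller contribution of such cells stays open. The effector minus resting score was 0.94, 0.27 and 0.38 in Srebp2WT and -0.64, -0.77 and -0.18 in Srebp2cKO (exact permutation p = 0.1, the smallest possible). A genotype effect may account for this, but with 3 libraries each, and with Cre dose differing along with Srebf2, it stays open.

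Large changes clustered on chromosomes: the most crowded window of 50 tested genes held 11, against a 95th percentile of 6 and a highest value of 8 in 1000 random placements. Reads shared between neighbouring paralogs as the cause of most of it are argued against, as 6 of the 28 clustered genes (21.4%, exact 95% upper bound 41.0%) had at least 10% of their 50-base words in transcripts of another gene of the same stretch, which leaves those 6 open, against 12.3% of the other tested genes there (Fisher's exact p = 0.230). A candidate explanation for the stretch around Srebf2 is DNA of another mouse strain carried along with the modified Srebf2 allele, which was tested on the 50 tested genes beside Srebf2 (80.6 to 84.2 Mb), a window that held 2 of the stretch's 8 other large changes and left out 6, Apobec3 and Cbx6 among them. They held 3 large changes (Tnfrsf13c, Bik and Nfam1, the last named after its values were seen). Random placements gave a mean of 1.04 and a highest of 6 (permutation p = 0.0799), so this test missed the threshold. The explanation stays open, since the stretch as a whole was picked for its large changes and no sequence was examined. The 2 stretches on chromosome 14 held 11 and 8 of the 28 clustered genes, Mtmr9 among them. Srebf2 lies on another chromosome, so DNA linked to its allele cannot account for these 2 stretches. Beyond shared reads and sterol-regulated genes lying together, no cause was tested for them. For sterol-regulated genes lying together, 0 of the 28 clustered genes were in the sterol or fatty acid lists, against 5 of 189 elsewhere (Fisher's exact p = 1), but chance alone would give only 0.645, too few to decide. Fdft1, a cholesterol synthesis gene that fell by 0.81 on the log2 scale, ends at 63179578 on chromosome 14. That is just before the second stretch there, which starts at 63182443. Its change was below the size that counted as large, so Fdft1 did not enter this test.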
